A study of Rattus norvegicus with 11 samples.

How the data were processed

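Single-cell 5′ RNA sequencing libraries of CD45-enriched cells from RG2 tumours were compared between 4 control, 4 pMBRT and 3 conventional PT libraries. The deposited matrices hold UMI counts per gene and barcode made with Cell Ranger, which the submitters' processing notes give as version 6.0.0. Per the file headers, these counts were made with version 6.0.0 in 6 early libraries and with version 7.0.1 in 5 late libraries. Genome build and annotation are not given in the sources used here, and Ensembl rat identifiers and symbols were taken as deposited. The 11 matrices held 74584 barcodes, 25399 features (99 duplicated symbols, kept apart by identifier) and 910635946 UMIs in all, with 32077896 to 158893110 per library. Library series was inferred from blocks of library numbers in the deposited file names before the data were examined, not from a stated batch, and the headers divide the libraries in the same way.

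Barcodes with fewer than 300 genes or 500 UMIs (1207 removed) or more than 15% of UMIs from 13 mitochondrial genes (4809) were left out, some for both reasons, which kept 69741. Doublets were called per library by scrublet in scanpy 1.11.5 at an expected 0.8% per 1000 barcodes and removed (3982, 2.80% to 8.55% per library), leaving 65759 cells. Counts were scaled to 10000 per cell and log-transformed. Clustering used the 2000 most variable genes within libraries (without mitochondrial, ribosomal, T cell receptor and immunoglobulin segment genes), 30 principal components and 15 neighbours. This gave 43 Leiden clusters at resolution 1 (igraph 0.11.9). A cluster was named when at least 3 markers of a class were detected in 10% or more of its cells and were 2-fold higher than in other cells, checked against its 10 leading genes. Clusters with markers of 1 class and leading genes of another were kept out of that class. Clusters with low UMI counts and no marker among their 10 leading genes stayed without a name. Names are rebuilt from markers and were not given by the submitters.

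Class sums of raw counts per library, from libraries with at least 20 cells, were tested for 4 classes. Sums ranged from 3528461 to 56221701 UMIs in macrophages, 2408354 to 28252380 in T/NK cells, 896451 to 28246658 in microglia and 2173154 to 12249744 in dendritic cells. Genes past filterByExpr were tested in edgeR 4.0.16 (TMM, robust quasi-likelihood F test) with group and library series over all 11 libraries, adjusted by Benjamini-Hochberg at 0.05. The p-values are two-sided. DESeq2 1.42.0 with the same design was an alternative. Standard errors are the log2 fold change over the square root of F, and intervals use 1.96 of them. CPM are TMM-scaled means per group. Shares were tested by edgeR on cell counts, for classes with at least 10 cells on average, and by exact permutation of the group labels. The permutation p-values are not adjusted over classes and take no account of the library series. Gene lists, 27 in all and fixed in advance, were tested with camera in limma 3.58.1 at a correlation between genes of 0.01 (prior count 2, at least 5 members), adjusted over 101 tests per comparison, and again with an estimated correlation. Named genes are the 4 with the largest fold change in each direction among those past the threshold with average log2 CPM of at least 5, without uncharacterised, mitochondrial, ribosomal protein and haemoglobin genes, and up to 4 with the smallest p of each described list. Members of a list counted over all genes passed the adjustment over every tested gene. A sterol synthesis list of 23 genes was written after the values of 9 of them had been seen.

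The alternatives were other scaling, a fit without series, 1 series alone, no expression filter, a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), doublets kept, resolution 0.5, corrected principal components, other denominators, a replicate block and leaving out each library. Replicate numbers shared between groups were checked as pairs. The lowest correlation of pairs' deviations was -0.17 in macrophages, -0.42 in T/NK cells, -0.21 in microglia and -0.22 in dendritic cells, below the 0.1 required, and the libraries were not treated as paired.

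The pipeline was tested on simulated counts of the same sizes with 200 changed genes. For pMBRT against control it recovered 1.49% to 4.48% of 1.5-fold changes, 34.3% to 53.7% of 2-fold changes and 77.3% to 89.4% of 4-fold changes over the 4 classes. For conventional PT against control these were 0% to 1.49%, 2.99% to 5.97% and 59.1% to 63.6%, and for pMBRT against conventional PT 0, 5.97% to 16.4% and 60.6% to 83.3%. Of the simulated calls 0 to 10.7% were false. The simulated libraries shared a common mean profile with independent noise, without an effect of library series, cluster mix or free RNA. These rates therefore do not describe libraries that differ in such ways. Between libraries of a group, the chi-square per gene was at least 40.6 in 15 pairs, so no library is a copy of another. The lowest value was that of controls 1 and 2, and the next lowest was 159.9, for conventional PT 2 and 3. Whether controls 1 and 2 share an animal or pool was not stated. Gene tests were limited to the 4 most numerous named immune classes, and other classes were not analysed for genes here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3 were used.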

Results

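Immune cells of RG2 glioblastoma, a transplantable glioma grown in the brain of male Fischer rats, were profiled by 5′ single-cell RNA sequencing after magnetic enrichment for CD45, the pan-leukocyte surface antigen. The 11 libraries comprised 4 from untreated tumours collected 14 days after implantation, 4 collected 7 days after proton minibeam radiotherapy (pMBRT, in which the dose is delivered as an array of narrow beams) and 3 collected 7 days after conventional proton therapy (conventional PT). Control and irradiated tumours were therefore not described on the same time scale. The deposited UMI totals were 39195695, 33163311, 32077896 and 132182460 in controls 1 to 4, 79035234, 74728554, 64043583 and 136092416 in pMBRT 1 to 4, and 80049142, 158893110 and 81174545 in conventional PT 1 to 3. The libraries fell into an early series (controls 1 to 3 and pMBRT 1 to 3) and a late series (control 4, pMBRT 4 and all conventional PT libraries), separated by library numbers and by Cell Ranger version. Median UMIs per barcode ranged from 1952 to 6947.5 in the early and from 7904 to 14248.5 in the late libraries. Since the version changes with the series, a difference in depth could not be told apart from a difference in how reads were counted. This also limits comparisons of conventional PT, where all libraries are late, with the mostly early controls. Within the early series, the pMBRT libraries have consecutive library numbers apart from those of the controls. A batch within that series could therefore not be told apart from pMBRT. Separate animals were not stated, so p-values measure the spread between these samples.

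After filtering, 65759 cells were retained, between 3402 and 9777 per library. Clusters were named from fixed markers, and the microglia-like (6929 cells), monocyte/macrophage-like (13633), T/NK-like (16482) and conventional dendritic-like (4281) classes, named below without the suffix, were compared. Ptprc (ENSRNOG00000000655), which encodes CD45, was measured at 439 ± 97.7 CPM in controls (SD, n = 4), 580 ± 28.0 after pMBRT (n = 4) and 740 ± 219 after conventional PT (n = 3). Cells with tumour or glial markers, which the CD45 enrichment should remove, made up 9.42% ± 9.55 of control cells, 1.13% ± 0.459 after pMBRT and 0.716% ± 0.224 after conventional PT. Clusters 1, 29 and 42 carried macrophage markers but had a leading gene listed for another class, and were kept out of the macrophage class. In clusters 1 and 29 this gene was Pf4, listed with erythroid or platelet genes, and in cluster 42 Fcrla, listed with B cells. Apoe and Trem2 also led clusters 1 and 29, and the fixed macrophage markers Gpnmb and Mrc1 were among the leading genes of cluster 1. Together these clusters held 0.125% ± 0.125 of control cells, 6.91% ± 10.9 of pMBRT cells and 15.9% ± 4.88 of conventional PT cells. Clusters without a name held 9.96% ± 7.29, 40.9% ± 21.3 and 13.5% ± 4.80 of cells, respectively.

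The comparison of pMBRT with untreated tumours asked how minibeam irradiation changed the tumour-infiltrating immune cells. Microglia, the resident macrophages of the brain, made up 23.7% ± 8.44 of the cells of control tumours (SD, n = 4) and 3.80% ± 1.57 after pMBRT (n = 4). The share was lower in 4 of 4 pMBRT libraries than in any control, with a log2 fold change of -2.61 (SE 0.69, edgeR adjusted p = 0.0217, exact two-sided permutation p = 0.0286, the smallest that 70 permutations allow). It was 20.4% against 3.57% in the early libraries and 33.7% against 4.47% in the single late pair. Monocytes/macrophages made up 35.6% ± 8.38 of control and 16.0% ± 4.98 of pMBRT cells (38.1% and 18% early, 28.0% and 9.94% late). The difference passed the exact permutation test (two-sided p = 0.0286), which is not adjusted over classes and ignores the library series. It did not pass the model with the series (log2 fold change -1.18, SE 0.66, edgeR adjusted p = 0.237). With clusters 1, 29 and 42 joined to the class, an alternative added after the results were seen, the shares were 35.7% and 22.9% and neither test passed (log2 fold change -0.67, SE 0.49, edgeR adjusted p = 0.345, exact two-sided permutation p = 0.0857). T/NK cells made up 12.9% ± 4.74 and 24.4% ± 11.4 (13.7% and 18.9% early, 10.4% and 41.0% late), and the groups were not distinguished by either test (edgeR adjusted p = 0.259, exact two-sided permutation p = 0.0571). Conventional dendritic cells made up 6.22% ± 2.02 and 5.57% ± 1.38 (edgeR adjusted p = 0.780, exact two-sided permutation p = 0.600). The microglial call ended without control 3 (edgeR adjusted p = 0.0673), pMBRT 2 (0.0774) or pMBRT 3 (0.0654), with named immune cells as the denominator (log2 fold change -2.02, adjusted p = 0.0507), with TMM factors over classes (-1.78, adjusted p = 0.180), and with a Leiden resolution of 0.5 (-1.17, adjusted p = 0.204). These are shares of CD45-enriched cells past a UMI filter, in libraries of unequal UMI depth and different Cell Ranger versions.

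**Figure D1:**
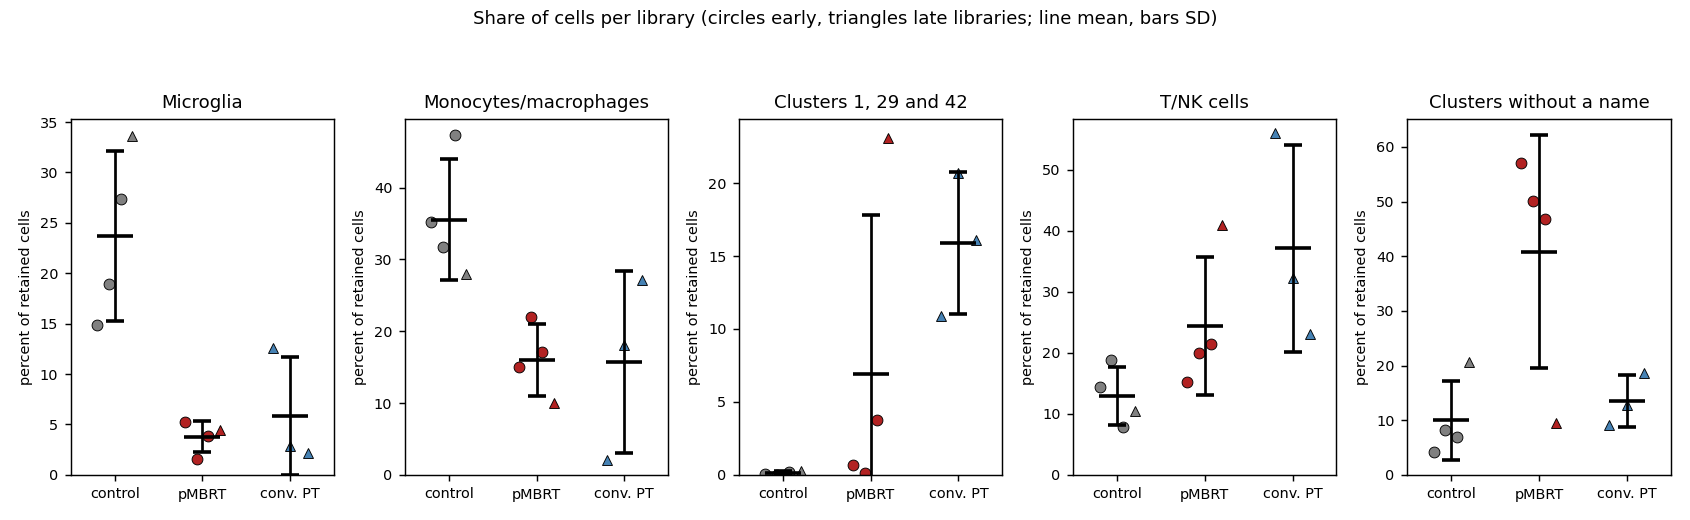
Percent of retained cells per library in microglia, monocytes/macrophages, clusters 1, 29 and 42, T/NK cells and the clusters without a name (vertical axes in percent, from 0), by group. Each point is 1 library (circles early, triangles late), the horizontal line is the group mean and the bars are the SD. The 4 pMBRT libraries hold between 1.60% and 5.26% microglia, all below the control libraries at 14.9% to 33.7%.

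Within the T/NK compartment, natural killer cells, cytotoxic innate lymphocytes, made up 2.25% ± 1.62 in controls and 0.410% ± 0.303 after pMBRT (SD, n = 4 each), a log2 fold change of -2.59 (SE 0.79, edgeR adjusted p = 0.0427, exact two-sided permutation p = 0.0571). The shares were 2.6% and 0.263% in the early libraries and 1.21% and 0.853% in the single late pair. CD8 T cells made up 4.19% ± 4.85 and 15% ± 14.2 of T/NK cells (edgeR adjusted p = 0.575), and these lay in lymphocyte cluster 15 in controls 1 to 4 and pMBRT 1 to 3 (at least 87.2% per library) but in cluster 0 in pMBRT 4 (99.8%). CD4 T, regulatory T and cycling cells did not pass the test either (edgeR adjusted p = 0.575 for each), and 46.9% ± 16.6 and 37.6% ± 12.1 of T/NK cells stayed without a subclass. The NK subclass was 1 lymphocyte cluster of 152 cells. Lymphocyte cluster 2, left without a subclass, has Klra22, Ly49s7 and Klrb1c, which encode NK receptors, among its leading genes and held 366 control and 641 pMBRT cells outside the NK count. The NK call rested on 17, 26, 2 and 9 cells in the control libraries and 2, 4, 4 and 27 in the pMBRT libraries. It ended without control 1 (edgeR adjusted p = 0.101), control 2 (0.107), pMBRT 1 (0.169), pMBRT 2 (0.165), pMBRT 3 (0.144), conventional PT 2 (0.0664) or conventional PT 3 (0.0534).

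In microglia, pMBRT was accompanied by higher transcripts of the p53 response, the program that follows DNA damage. Phlda3 (ENSRNOG00000009068), a p53-induced repressor of Akt signalling, rose from 6.15 ± 1.80 CPM to 108 ± 17.7 (SD, n = 4 each), a log2 fold change of 4.08 (SE 0.35, edgeR adjusted p = 0.000238). Cdkn1a (ENSRNOG00000000521), which encodes the cell cycle inhibitor p21, rose from 182 ± 91.1 to 1616 ± 343 CPM (3.21, SE 0.44, edgeR adjusted p = 0.00857). Mmp2 (ENSRNOG00000016695), a gelatinase, rose from 15.3 ± 1.91 to 219 ± 78.5 CPM (3.85, SE 0.34, edgeR adjusted p = 0.000238), and Mgmt (ENSRNOG00000016038), which repairs alkylated guanine, rose from 16.5 ± 12.8 to 130 ± 50.7 CPM (3.15, SE 0.26, adjusted p = 0.000184). Arl5c (ENSRNOG00000036880), a small GTPase, fell by 1.59 on the log2 scale (SE 0.25, edgeR adjusted p = 0.0101), as did C3ar1 (ENSRNOG00000009211), the receptor of complement fragment C3a (-1.35, SE 0.26, adjusted p = 0.0253), Hivep3 (ENSRNOG00000009341, -1.30, SE 0.25, adjusted p = 0.0239) and Nt5dc2 (ENSRNOG00000018358, -1.21, SE 0.22, adjusted p = 0.0206). For each of these 8 genes, 4 of 4 pMBRT libraries lay beyond every control. Most microglia of controls 1 to 3 lay in cluster 11 (69.7% to 95.2%) and those of control 4 in cluster 10 (83.5%), whereas the largest cluster was 17 in pMBRT 1 and 3 (55.2% and 52.5%), 10 in pMBRT 2 (49.1%) and 28 in pMBRT 4 (53.6%). Mmp2 was among the leading genes of clusters 17 and 28, and Nt5dc2 of cluster 10.

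Of 23 measured p53 targets, 8 rose and 0 fell in microglia over all genes, and 13 rose adjusted over the list alone. Besides Phlda3 and Cdkn1a they included Tp53inp1 (ENSRNOG00000007964, 2.63, SE 0.46, edgeR adjusted p = 0.0212) and Sesn2 (ENSRNOG00000042785, 1.38, SE 0.24, adjusted p = 0.0172), each beyond every control in 4 of 4 pMBRT libraries. The list median was 1.00 with 19 of 23 fold changes positive (camera adjusted p = 5.86e-09, adjusted p = 0.326 with an estimated correlation), and it was 0.94 in the early and 1.11 in the late libraries. Log2 fold changes in the early and late libraries were 4.23 and 3.61 for Phlda3, 2.96 and 3.92 for Cdkn1a, 3.74 and 4.12 for Mmp2, and 3.40 and 2.46 for Mgmt.

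Of 16 genes listed for MHC class II antigen presentation to CD4 T cells, 1 rose in microglia over all genes. It was Cd80 (ENSRNOG00000001527), a costimulatory ligand and not a class II molecule (1.71, SE 0.26, edgeR adjusted p = 0.00965, 4 of 4 libraries beyond every control). Adjusted over the list alone, 10 rose and 1 fell. The list median was 1.66 (camera adjusted p = 4.06e-06, adjusted p = 0.375 with an estimated correlation), with 1.92 in the early and 0.29 in the late libraries. Of 27 genes of lipid handling and disease-associated microglia, 3 rose and 0 fell (5 and 1 adjusted over the list alone): Lyz2 (ENSRNOG00000005825), lysozyme, by 2.35 (SE 0.38, edgeR adjusted p = 0.0153), Cd68 (ENSRNOG00000037563), a lysosomal protein, by 1.08 (SE 0.20, adjusted p = 0.0239), and Igf1 (ENSRNOG00000004517), a growth factor, by 0.89 (SE 0.17, adjusted p = 0.0256), beyond every control in 3, 4 and 4 of 4 pMBRT libraries. That list's median was 0.22 (camera adjusted p = 0.0334, adjusted p = 0.437 with an estimated correlation), and the call ended without control 4 (adjusted p = 0.542) or pMBRT 4 (0.473). Lyz2 is also a fixed monocyte/macrophage marker, and whether macrophages were counted as microglia stays open (below). Of 18 homeostatic microglia genes, 0 passed over all genes and 6 fell adjusted over the list alone, with a median of -0.70 and 16 of 18 values negative (camera adjusted p = 8.45e-05, adjusted p = 0.379 with an estimated correlation). P2ry12 (ENSRNOG00000013902), a purine receptor, had a log2 fold change of -1.08 (SE 0.28, edgeR adjusted p = 0.0909). Markers of T and NK cells had a median of 1.15 in microglia, with 13 of 14 positive (camera adjusted p = 0.00481, adjusted p = 0.466 with an estimated correlation, 0.0852 without control 3).

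Over all 10695 genes tested in microglia, 106 rose and 31 fell after pMBRT (edgeR quasi-likelihood, adjusted p under 0.05). The total of 137 became 38 without control 1, 85 without control 2, 79 without control 3, 400 without control 4, 66 without pMBRT 1, 66 without pMBRT 3 and 392 without pMBRT 4. It was 336 in the early libraries, which held 101 of the 137 calls. In the late libraries 1 control and 1 pMBRT library are compared and their spread is taken from the conventional PT libraries. The late libraries therefore could not test these calls again. Among the named genes, the calls of Phlda3, Cdkn1a, Mmp2, Mgmt, Arl5c and Cd80 held without any single library, and those of Sesn2 and Tp53inp1 ended, among others, without control 1 (edgeR adjusted p = 0.0805 for each). Without control 1 the calls of C3ar1 (0.0805), Hivep3 (0.0816), Nt5dc2 (0.0612), Lyz2 (0.0805), Cd68 (0.131) and Igf1 (0.0805) ended too.

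**Figure D2:**
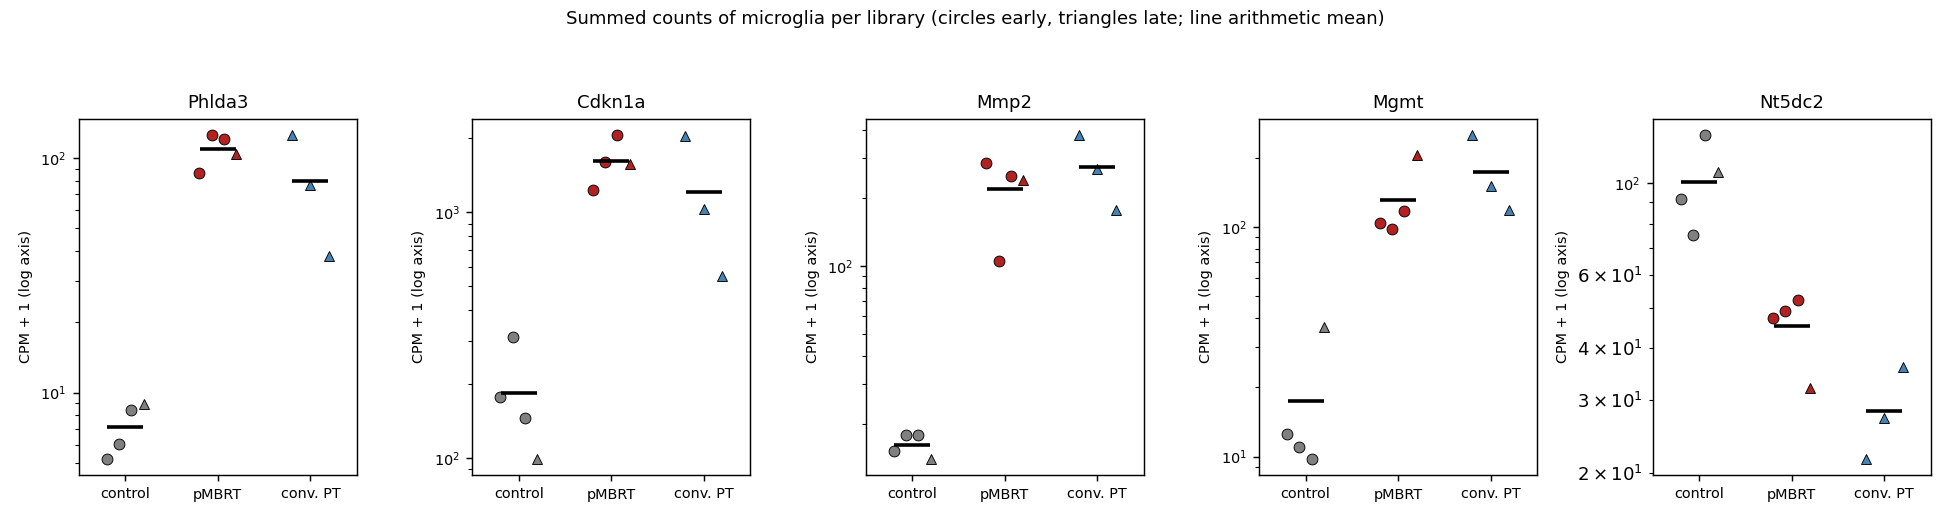
CPM + 1 of Phlda3, Cdkn1a, Mmp2, Mgmt and Nt5dc2 in the summed counts of microglia per library (vertical log axes that differ between genes), by group. Each point is 1 library (circles early, triangles late) and the horizontal line is the arithmetic mean. Phlda3 averages 6.15 CPM in controls, 108 after pMBRT and 78.7 after conventional PT.

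The interferon gamma response and MHC class I lists had higher medians after pMBRT in the early libraries, whereas in the single late pair their medians lay between -0.71 and 0.04. The early pMBRT libraries are also those in which the low-UMI clusters 2, 6 and 12, outside the 4 classes, held at least 33.6% of cells, and Cxcl11 and Ifng are among the leading genes of clusters 6 and 12. The interferon gamma list had a median log2 fold change of 1.54 in microglia (20 of 21 positive, camera adjusted p = 1.84e-07, adjusted p = 0.427 with an estimated correlation), with 2.17 in the early and -0.71 in the late libraries. It was 1.58 in macrophages (22 of 22 positive, camera adjusted p = 1.93e-11, adjusted p = 0.393 with an estimated correlation), with 2.10 early and -0.29 late. It was 1.25 in dendritic cells (21 of 22 positive, camera adjusted p = 2.45e-05, adjusted p = 0.471 with an estimated correlation), with 1.78 early and -0.63 late, and 0.51 in T/NK cells (21 of 22 positive, camera adjusted p = 2.88e-05, adjusted p = 0.427 with an estimated correlation), with 0.61 early and -0.16 late. No member passed over all genes in any of the 4 classes, where 0, 18, 9 and 2 rose adjusted over the list alone. Irf1 (ENSRNOG00000008144), an interferon-induced transcription factor, had a log2 fold change of 1.58 in macrophages (SE 0.45, edgeR adjusted p = 0.214), with 2.07 early and -0.04 late. The MHC class I list had medians of 0.79 in microglia (1.20 early, -0.41 late), 0.80 in macrophages (1.04 early, -0.19 late), 0.63 in dendritic cells (0.75 early, 0.01 late) and 0.36 in T/NK cells (0.33 early, 0.04 late), with adjusted p-values of 5.86e-09, 5.86e-09, 6.98e-07 and 5.75e-06 by camera and adjusted p = 0.379, 0.423, 0.379 and 0.363 with an estimated correlation. Of its members only RT1-M3-1 (ENSRNOG00000000763, 0.82, SE 0.14, edgeR adjusted p = 0.0356) and RT1-CE5 (ENSRNOG00000000723, 0.81, SE 0.16, adjusted p = 0.0485) passed over all genes, in dendritic cells and beyond every control in 4 of 4 libraries. Their fold changes were 0.84 and 0.74 in the early and 0.74 and 1.02 in the late libraries. Adjusted over the list alone 11, 12, 13 and 4 rose in the 4 classes. RT1 class I genes are near-identical paralogs, and their values are reported as uncertain.

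In conventional dendritic cells, which present antigen to T cells, 3 of the named genes that fell after pMBRT encode enzymes of sterol synthesis. Cyp51 (ENSRNOG00000007234), lanosterol demethylase, fell from 82.7 ± 26 CPM to 19.4 ± 5.95 (SD, n = 4 each, log2 fold change -2.05, SE 0.25, edgeR adjusted p = 0.0205). Idi1 (ENSRNOG00000016690), isopentenyl diphosphate isomerase, fell from 71.4 ± 6.53 to 25.5 ± 10.0 CPM (-1.59, SE 0.25, edgeR adjusted p = 0.0282), and Hmgcs1 (ENSRNOG00000016552), a synthase of the mevalonate pathway, from 113 ± 37.3 to 41.6 ± 11 CPM (-1.45, SE 0.20, adjusted p = 0.0205). Fcrla (ENSRNOG00000003136), an Fc receptor-like protein, fell by 1.49 (SE 0.22, edgeR adjusted p = 0.0249). Chac1 (ENSRNOG00000014387), which degrades glutathione, rose by 2.46 (SE 0.47, edgeR adjusted p = 0.0474), Tcf7 (ENSRNOG00000005872), a transcription factor, by 2.07 (SE 0.33, adjusted p = 0.0282), Sh3bp4 (ENSRNOG00000019316) by 1.76 (SE 0.34, adjusted p = 0.0474) and Abcg1 (ENSRNOG00000001158), a cholesterol exporter, by 1.73 (SE 0.34, adjusted p = 0.0474). For each of these 8 genes 4 of 4 pMBRT libraries lay beyond every control, and the fold changes in the early and late libraries had the same sign (Cyp51 -2.21 and -1.57, Tcf7 2.21 and 1.72). The largest dendritic cluster was 22 in controls 1 to 3 (36.0% to 55.1%), 24 in control 4 (51.4%) and pMBRT 3 (35.4%), 20 in pMBRT 1 and 2 (48.0% and 43.6%) and 21 in pMBRT 4 (41.6%). Whether the genes changed within a cluster was not tested. Tcf7 is also among the leading genes of T/NK cluster 14, and 13 of 15 markers of T and NK cells had positive fold changes in these dendritic sums (below).

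Of 27 inflammatory cytokines and NF-kB targets, 2 rose and 0 fell in dendritic cells, and 6 rose adjusted over the list alone. Relb (ENSRNOG00000033235), an NF-kB subunit, rose by 1.37 (SE 0.23, edgeR adjusted p = 0.0349, 1.60 early, 0.70 late) and Birc3 (ENSRNOG00000005731), an inhibitor of apoptosis induced by NF-kB, by 0.87 (SE 0.16, adjusted p = 0.0421, 1.00 early, 0.49 late), each beyond every control in 4 of 4 pMBRT libraries. The list median was 0.68 (camera adjusted p = 0.000716, adjusted p = 0.466 with an estimated correlation), with 0.98 in the early and -0.29 in the late libraries. Markers of T and NK cells had a median of 1.55 in dendritic cells, with 13 of 15 positive (camera adjusted p = 0.00298, adjusted p = 0.474 with an estimated correlation). Without control 4 or pMBRT 4 the adjusted p was 0.127 or 0.130. Over all 10928 genes, 68 rose and 28 fell (edgeR), but the total of 96 became 0 without control 1, control 2 or pMBRT 2, 4 without pMBRT 3, 18 without pMBRT 1, 257 without control 3, 1155 without control 4 and 1158 without pMBRT 4. It was 852 in the early libraries, which held 92 of the 96 calls. The late libraries compare 1 control with 1 pMBRT library and could not test these calls again. Without the series covariate 41 of the 96 calls held, and DESeq2 or no expression filter gave more genes (below).

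**Figure D3:**
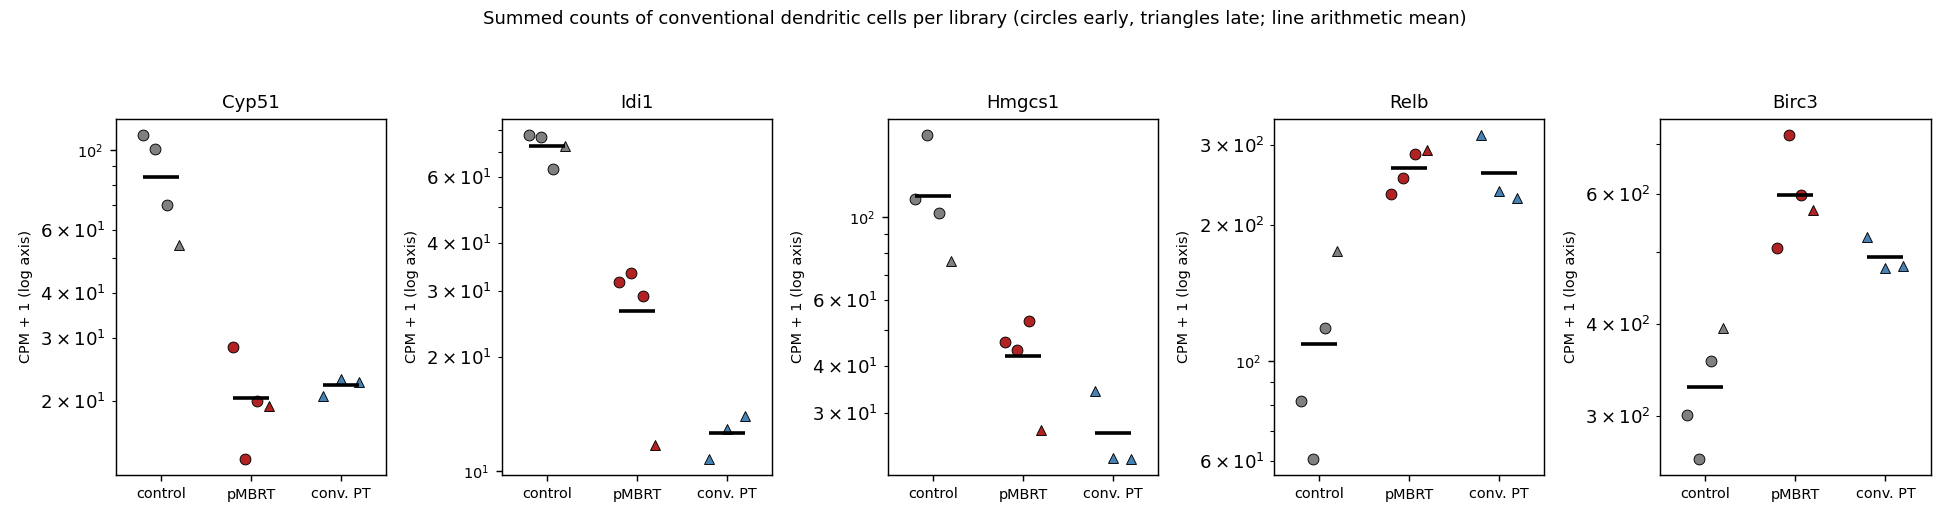
CPM + 1 of Cyp51, Idi1, Hmgcs1, Relb and Birc3 in the summed counts of conventional dendritic cells per library (vertical log axes that differ between genes), by group. Each point is 1 library (circles early, triangles late) and the horizontal line is the arithmetic mean. Cyp51 averages 82.7 CPM in controls, 19.4 after pMBRT and 21.2 after conventional PT.

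In monocytes/macrophages, 2 of 11953 genes rose and 3 fell after pMBRT (edgeR). Med13 (ENSRNOG00000003679), a subunit of the Mediator complex, fell from 51.0 ± 4.13 to 23.1 ± 4.12 CPM (SD, n = 4 each, log2 fold change -1.15, SE 0.13, edgeR adjusted p = 0.0151, -1.27 early, -0.78 late, 4 of 4 libraries beyond every control). The largest macrophage cluster was 5 in controls 1 to 3 (45.7% to 77.6%) and pMBRT 1 (40.6%), and 0 in control 4 (69.6%) and pMBRT 2 to 4 (55.4% to 62.4%). The other genes, named here after their values were seen, were Cd101 (ENSRNOG00000037190, -1.50), the uncharacterised AABR07070335.1 (ENSRNOG00000053878, -4.64), Impdh1 (ENSRNOG00000020032, 1.24), an enzyme of guanine nucleotide synthesis, and Mcoln2 (ENSRNOG00000015089, 1.53), a lysosomal cation channel. The total of 5 became 0 without control 1, control 2, pMBRT 2 or pMBRT 3, 8 without pMBRT 1, 503 without control 4 and 527 without pMBRT 4. It was 0 in the early libraries and 360 by DESeq2. The late libraries compare 1 control with 1 pMBRT library and could not test these calls again. Dissociation stress and immediate early genes had a median of 0.47 (24 of 26 positive, camera adjusted p = 4.43e-07, adjusted p = 0.305 with an estimated correlation), with 0.57 early and 0.10 late. Over the list alone 2 rose. Fos (ENSRNOG00000008015) had a log2 fold change of 1.03 (SE 0.21, edgeR adjusted p = 0.134). In the same macrophage sums, markers of tumour cells and glia had a median of -0.75 (11 of 15 negative, camera adjusted p = 0.00127, adjusted p = 0.305 with an estimated correlation, 0.0972 without control 4) and markers of T and NK cells a median of 1.08 (10 of 13 positive, camera adjusted p = 0.0134, adjusted p = 0.427 with an estimated correlation). The latter call ended without control 3 (0.0669), control 4 (0.151) or pMBRT 4 (0.161).

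In T/NK cells, edgeR called 0 of 12316 genes after pMBRT, with 1536 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0507, whereas DESeq2 called 243. Proliferation genes had negative values in 34 of 34 members, with a median of -1.05 (camera adjusted p = 1.26e-07, adjusted p = 0.516 with an estimated correlation). The median was -0.36 in the early and -3.96 in the late libraries, and the adjusted p was 0.0894 without control 4 and 0.0958 without pMBRT 4. Cycling cluster 13 held 24.6% to 27.0% of the T/NK cells of controls and 18.9% to 23.5% of those of pMBRT 1 to 3, but 0.569% in pMBRT 4, where cluster 4 was the largest (41.0%). Dissociation stress and immediate early genes had a median of 0.74, with 21 of 26 positive (camera adjusted p = 2.70e-08, adjusted p = 0.305 with an estimated correlation), 0.72 early and 0.48 late. Adjusted over the list alone 13 rose, and Atf3 (ENSRNOG00000003745), a stress-induced transcription factor, had a log2 fold change of 1.71 (SE 0.30, edgeR adjusted p = 0.147). Homeostatic microglia genes, which T/NK cells should lack, had a median of -0.85 in the T/NK sums (2 rose and 7 fell adjusted over the list alone, 13 of 16 negative, camera adjusted p = 5.43e-05, adjusted p = 0.305 with an estimated correlation). For example, Sparc (ENSRNOG00000012840) measured 19.5 ± 5.61 CPM in controls and 3.52 ± 1.03 after pMBRT (SD, n = 4 each). Without control 3, edgeR called 1 gene. The early libraries gave 2.

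The comparison of conventional PT with untreated tumours asked the same question for broad-field irradiation. T/NK cells made up 37.2% ± 16.9 of cells after conventional PT (SD, n = 3) against 12.9% ± 4.74 in controls (n = 4), and monocytes/macrophages 15.8% ± 12.7 against 35.6% ± 8.38. Each difference passed the exact two-sided permutation test (p = 0.0286, the smallest that 35 permutations allow), which is not adjusted over classes. That test ignores the library series, and all conventional PT libraries but only 1 control are late, so it cannot separate treatment from series. Neither difference passed the model with the series (edgeR, log2 fold change 1.15, SE 0.78, adjusted p = 0.399 for T/NK cells, -0.68, SE 0.88, adjusted p = 0.463 for macrophages). With clusters 1, 29 and 42 joined to the macrophages, added after the results were seen, the macrophage shares were 31.7% and 35.7% and neither test passed (log2 fold change -0.35, SE 0.69, edgeR adjusted p = 0.619, exact two-sided permutation p = 0.714). Microglia made up 5.86% ± 5.84, a log2 fold change of -2.38 (SE 0.88) that did not pass (edgeR adjusted p = 0.142, exact two-sided permutation p = 0.0571). Without conventional PT 1, the library with 12.6% microglia, the value was -3.61 (edgeR adjusted p = 0.00406). Dendritic cells made up 8.54% ± 2.79 (edgeR adjusted p = 0.463). The only late control held 33.7% microglia, 28.0% macrophages and 10.4% T/NK cells. Plasmacytoid dendritic cells passed only without control 4 (log2 fold change -6.20, edgeR adjusted p = 0.0375). No lymphocyte subclass passed (edgeR, lowest adjusted p = 0.705, for NK cells). Cycling cells made up 21.2% ± 3.52 of control T/NK cells and 7.22% ± 7.43 after conventional PT (exact two-sided permutation p = 0.0286, edgeR adjusted p = 0.840).

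In microglia, 17 of 10695 genes rose and 2 fell after conventional PT (edgeR). Mmp2 rose to 273 ± 102 CPM (SD, n = 3, log2 fold change 4.21, SE 0.49, edgeR adjusted p = 0.00894) and Phlda3 to 78.7 ± 43.3 CPM (3.55, SE 0.47, adjusted p = 0.0110). Csrp2 (ENSRNOG00000003772), a LIM domain protein, rose from 8.98 ± 2.13 to 55.2 ± 16.5 CPM (3.08, SE 0.42, edgeR adjusted p = 0.0110), Mgmt rose to 172 ± 69.4 CPM (2.57, SE 0.35, adjusted p = 0.0110), and Nt5dc2 fell to 27.2 ± 7.22 CPM (-1.77, SE 0.30, adjusted p = 0.0439). For each of these 5 genes, 3 of 3 conventional PT libraries lay beyond every control. Clusters 17 (57.8% ± 11.6) and 28 (27.1% ± 7.60) held most microglia after conventional PT (mean of libraries). Mmp2 is among the leading genes of both clusters, and Nt5dc2 of cluster 10, in which 83.5% of cells came from control 4. Of 23 p53 targets 1 rose over all genes and 9 adjusted over the list alone, with a median of 0.94 and 20 of 23 values positive (camera adjusted p = 8.71e-11, adjusted p = 0.222 with an estimated correlation). In the late libraries the median was 0.99. Cdkn1a measured 1205 ± 762 CPM (3.17, SE 0.64) and did not pass (edgeR adjusted p = 0.138). The total of 19 became 0 without control 4, 9 without control 1, 10 without control 3, 8 without conventional PT 1 and 4 without conventional PT 2. It was 0 within the late libraries, against their only control. Without control 4 the calls of Mmp2 (edgeR adjusted p = 0.234), Phlda3 (0.234), Csrp2 (0.272), Mgmt (0.0827) and Nt5dc2 (0.429) all ended.

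Markers of T and NK cells had a median of 1.86 in microglia after conventional PT (12 of 14 positive, camera adjusted p = 0.0115, adjusted p = 0.553 with an estimated correlation). The call ended without control 4 (0.190), conventional PT 1 (0.124) or conventional PT 3 (0.0512). Inflammatory cytokines and NF-kB targets had a median of -0.54 in microglia (24 of 27 negative, camera adjusted p = 0.000217, adjusted p = 0.436 with an estimated correlation, 0.353 without control 4), where Nfkbiz (ENSRNOG00000031163), an NF-kB regulator, had a log2 fold change of -1.02 (SE 0.21, edgeR adjusted p = 0.116). In macrophages the same list had a median of 0.63 (26 of 27 positive, camera adjusted p = 1.75e-09, adjusted p = 0.0955 with an estimated correlation), with 0.53 in the late libraries. In macrophages Traf1 (ENSRNOG00000048914), a signalling adaptor, had a log2 fold change of 1.85 (SE 0.40, edgeR adjusted p = 0.537). When adjusted over the list alone, 1 member fell in microglia and 1 rose in macrophages. Type I interferon genes had medians of -0.65 in T/NK cells (30 of 33 negative, camera adjusted p = 7.19e-08, adjusted p = 0.553 with an estimated correlation) and -0.85 in dendritic cells (30 of 33 negative, camera adjusted p = 6.52e-07, adjusted p = 0.553 with an estimated correlation). Without control 4 these medians were 0.42 and 0.85, so their direction rested on that library. Adjusted over the list alone, 0 passed in T/NK cells and 4 fell in dendritic cells.

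After conventional PT, edgeR called 0 genes in macrophages (539 at an unadjusted p under 0.05), 0 in T/NK cells (269) and 0 in dendritic cells (675), where DESeq2 called 31, 14 and 42. In conventional PT 1 to 3 the largest macrophage cluster was 0 (84.8%, 52.3% and 47.8%), the largest T/NK clusters were 4 (53.6%), 9 (16.8%) and 13 (20.7%), and the largest dendritic clusters were 21 (55.1%), 21 (37.7%) and 20 (29.5%). Markers of tumour cells and glia had a median of -0.65 in macrophages (14 of 15 negative, camera adjusted p = 0.00118, adjusted p = 0.0955 with an estimated correlation, 0.187 without control 4), and homeostatic microglia genes a median of -0.78 in T/NK cells (13 of 16 negative, camera adjusted p = 3.43e-09, adjusted p = 0.0955 with an estimated correlation). Of these members, 1 and 4 fell adjusted over the list alone. In dendritic cells Cyp51, Idi1 and Hmgcs1 measured 21.2 ± 1.24, 11.6 ± 1.63 and 25.6 ± 6.69 CPM (SD, n = 3), and these genes did not pass. Without control 4 edgeR called 1 gene in macrophages and without control 3 it called 1 in T/NK cells. Within the late libraries it called 5 in dendritic cells.

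The comparison of pMBRT with conventional PT asked whether spatial fractionation of the dose changed the response. No class or lymphocyte subclass differed in share (edgeR adjusted p = 0.963 for each of 7 classes and 0.944 for each of 5 subclasses). Microglia made up 3.80% ± 1.57 of cells after pMBRT (SD, n = 4) and 5.86% ± 5.84 after conventional PT (n = 3, exact two-sided permutation p = 0.714), and T/NK cells 24.4% ± 11.4 and 37.2% ± 16.9 (exact two-sided permutation p = 0.314). The late pMBRT library held 4.47% microglia and 41.0% T/NK cells. edgeR called 0 genes in macrophages (158 at an unadjusted p under 0.05), T/NK cells (95), microglia (173) and dendritic cells (164), and DESeq2 called 0 in each. In dendritic cells 228 genes passed without pMBRT 4, the only late pMBRT library, whose omission left pMBRT and conventional PT without a shared series. Phlda3 in microglia had a log2 fold change of 0.54 (SE 0.42, edgeR adjusted p = 1.00), and the p53 list a median of -0.09 with 10 of 23 values positive (camera adjusted p = 0.985, 0.995 with an estimated correlation, median 0.21 and adjusted p = 0.0445 without conventional PT 1).

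The interferon gamma list had a median of 1.5 in microglia between pMBRT and conventional PT (21 of 21 positive, camera adjusted p = 7.39e-08, adjusted p = 0.620 with an estimated correlation) and 1.03 in dendritic cells (21 of 22 positive, camera adjusted p = 7.19e-06, adjusted p = 0.678 with an estimated correlation). In the late libraries, where pMBRT 4 is the only pMBRT library, the medians were -0.07 and -0.10. The relation was therefore not seen in the 1 series that holds both treatments, but this rests on 1 pMBRT library. Type I interferon genes had a median of 0.79 in microglia (33 of 33 positive, camera adjusted p = 6.37e-05, adjusted p = 0.678 with an estimated correlation) and -0.25 in the late libraries. Inflammatory cytokines and NF-kB targets had a median of 0.82 in dendritic cells (27 of 27 positive, camera adjusted p = 7.15e-09, adjusted p = 0.481 with an estimated correlation), with 0.13 in the late libraries. Ccl4 (ENSRNOG00000011406), a chemokine, had a log2 fold change of 1.85 in dendritic cells (SE 0.64, edgeR adjusted p = 1.00). Immediate early and dissociation stress genes had a median of 0.41 in T/NK cells (25 of 26 positive, camera adjusted p = 9.44e-11, adjusted p = 0.481 with an estimated correlation), with 0.36 in the late libraries. Proliferation genes in T/NK cells had a median of -0.80 (33 of 34 negative, camera adjusted p = 7.19e-06, adjusted p = 0.734 with an estimated correlation), which was 0.64 without pMBRT 4 and -0.17 without conventional PT 3 (adjusted p = 0.890). Of the lists of this comparison, 0 members passed over all genes or adjusted over the list alone.

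Over the gene lists, camera called 53 of 101 tests for pMBRT against control, 50 for conventional PT against control and 39 for pMBRT against conventional PT. With an estimated correlation it called 0, 0 and 0, with smallest adjusted p-values of 0.305, 0.0955 and 0.481.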

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

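The tests of the low-UMI clusters by library series and by pMBRT itself, the tests of the microglial share with named cells as the denominator and of dilution by T and NK cells, the tests of the p53 targets, and the gene-count splits of the libraries were chosen only after the results were seen. Values are given here when a library lies far from the others of its group (Dixon's test at the 95% level, in groups of 4), when an effect differs between the library series, or when a signal lies in cells that the comparisons leave out. By chance about 1 in 20 groups is marked, and 6 of 78 were.

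In pMBRT 4, the only late pMBRT library, B cells made up 2.5% of cells, against 0.0892% in the nearest pMBRT library. Clusters 1, 29 and 42 made up 23.1% of pMBRT 4, against 3.73%, and endothelial or mural cells 0.570%, against 0.125%. Control 4, the only late control, held 132182460 UMIs, against 39195695. Its microglia had 35.5 CPM of Mgmt, against 11.5 in the nearest control. Csrp2 reached 73.5 CPM in the microglia of pMBRT 3, against 35.4. For the effect of pMBRT between the library series, an interaction term passed for 2 genes in macrophages (1888 at an unadjusted p under 0.05) and 32 in dendritic cells (2042). In edgeR it passed for 0 in T/NK cells (1595, smallest adjusted p = 0.382) and 0 in microglia (1302, smallest adjusted p = 0.175). No other tool was run there. Tested were 11953 genes in macrophages, 10928 in dendritic cells, 12316 in T/NK cells and 10695 in microglia. In each class the unadjusted counts exceed a share of 0.05, so 0 calls do not show a like effect in both series.

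Clusters 2, 6 and 12, left without a name, held at least 33.6% of the cells of each of pMBRT 1 to 3, and at most 0.235% of any early control. A planned test of pairs of T cell and macrophage transcripts was void, since every barcode held macrophage transcripts, and a dispersion test with bounds written before it ran took its place. The T cell part of these transcripts varied between barcodes by a chi-square of 1.34 per barcode, against 17.9 to 23.3 in named cells thinned to 1460 UMIs. Barcodes holding free RNA or merged droplets would give such a low value. The named cells hold separate T/NK and macrophage classes, whereas these clusters were formed by like expression. A uniform kind of low-UMI cell would therefore also vary little, and the test cannot separate these explanations. The early series alone is argued against by the 0.235%. Minibeam irradiation as the source could not be told apart from a fault shared by 3 libraries, since pMBRT 4 held 0.0906%.

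The lower microglial share after pMBRT was weighed against 3 technical explanations. Among named immune cells the log2 fold change was -2.02 (SE 0.686), with an upper 95% limit of -0.68, whereas low-UMI barcodes in the denominator as the whole cause would leave it near 0. Its adjusted p was 0.0507, so its call ended. Dilution by T and NK cells alone is argued against by the log2 ratio of microglia to all cells with macrophage markers, which differed by -2.04. A score of 12 microglial markers over all cells minus that within the class differed by -0.66 between pMBRT and control, which leaves open whether microglia may be hidden in unnamed clusters. A loss of microglia after irradiation remains a hypothesis.

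The higher p53 targets in pMBRT microglia were weighed next. The tests on macrophages and clusters first ran on the 8 members that rose, which were chosen for the pattern, and were replaced by tests over all 23. In the pMBRT libraries these members were higher in microglia than in macrophages by a median log2 ratio of 0.83 (0.414 to 0.842 over libraries, 19 of 23 above 0). The lowest library missed the bound set for excluding macrophages counted as microglia, so this stays open. Within 3 microglial clusters with 2 or more libraries of each group, the members differed between pMBRT and control by a median of 0.462 in cluster 17 (14 of 23 above 0) to 1.38 in cluster 11. Another mix of microglial clusters therefore stays open for part of the difference. A shift between the library series as the cause is argued against by the list median, which was at least 0.94 in each series. A batch within the early series could not be told apart from pMBRT, and the late series holds a single pair of these groups. A response of microglia to radiation and the time since implantation stay untested.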

How the results depend on the processing

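The tests on late libraries only, early libraries only (shares and gene lists), late libraries for lists, named immune cells as the denominator, and with clusters 1, 29 and 42 joined were chosen only after the results were seen, and the others were written before the data were examined. Unless stated, the cause was not tested.

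Gene counts of pMBRT against control (5 in macrophages, 0 in T/NK cells, 137 in microglia, 96 in dendritic cells) moved as follows. DESeq2 gave 360, 243, 490 and 864. With no expression filter, macrophages gave 11, T/NK cells 2 and dendritic cells 209. Without the series covariate, microglia gave 72 and dendritic cells 41. In the early libraries (one library series) macrophages gave 0, T/NK cells 2, microglia 336 and dendritic cells 852. Counts in late libraries only compare 1 control with 1 pMBRT library and are not given. With clusters 1, 29 and 42, macrophages gave 3. Leaving out 1 library gave 0 to 527 in macrophages, 0 to 1 in T/NK cells, 38 to 400 in microglia and 0 to 1158 in dendritic cells.

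For conventional PT against control (0, 0, 19 and 0), DESeq2 gave 31, 14, 91 and 42. Without the series covariate, microglia gave 82 and dendritic cells 23. With no expression filter, dendritic cells gave 9. In the late libraries (one library series) microglia gave 0 and dendritic cells 5. Leaving out 1 library gave 0 to 1 in macrophages, 0 to 1 in T/NK cells, 0 to 26 in microglia and 0 to 0 in dendritic cells. For pMBRT against conventional PT (0 in each by edgeR and by DESeq2, with 158, 95, 173 and 164 at an unadjusted p under 0.05), no expression filter gave 3 in microglia and 3 in dendritic cells. The late libraries (one library series) gave 1 in macrophages, 2 in microglia and 5 in dendritic cells. Leaving out 1 library gave 0 to 228 in dendritic cells and 0 to 0 in the other classes.

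The replicate numbers do not pair the libraries (lowest correlation -0.42), and the replicate block in place of the series is given here only. For pMBRT against control it gave 0 genes in macrophages, 76 in microglia and 0 in dendritic cells. For conventional PT against control it gave 1054, 2105, 898 and 877 in macrophages, T/NK cells, microglia and dendritic cells, and for pMBRT against conventional PT 491, 1149, 208 and 432. Under each shared replicate number the conventional PT library is late and the control and pMBRT libraries are early. With the block, both comparisons therefore cannot separate treatment from library series. The block gave 31 list calls for conventional PT against control, and these calls and the medians below share that limit. List medians with the block were 0.0065 for chemokines and 0.076 for NF-kB targets in macrophages and 0.82 for proliferation in T/NK cells (pMBRT against conventional PT), and -0.079 for cytotoxicity in T/NK cells (conventional PT against control). The NK fold change was -2.55, with 0 subclasses past the threshold, and with controls and pMBRT only -2.32, with 0.

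List calls fell from 53, 50 and 39 to 0, 0 and 0 with an estimated correlation. Leaving out 1 library gave 35 to 59, 36 to 56 and 32 to 43. In late libraries only, for pMBRT against control, medians reversed to -0.41 (MHC class I, microglia), -0.19 (MHC class I, macrophages), -0.71, -0.63, -0.29 and -0.16 (interferon gamma in microglia, dendritic cells, macrophages and T/NK cells) and -0.29 (NF-kB targets, dendritic cells). In the late libraries, MHC class I reversed to -0.29 in microglia and -0.0095 in dendritic cells for conventional PT against control. For pMBRT against conventional PT, interferon gamma reversed to -0.071 in microglia, -0.10 in dendritic cells and -0.32 in macrophages, MHC class I to -0.094 in microglia, and type I interferon to -0.25 in microglia and -0.17 in T/NK cells.

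Without the series covariate, medians reversed to -0.031 for cytotoxicity in T/NK cells (conventional PT against control), 0.062 for chemokines in macrophages and 0.48 for proliferation in T/NK cells (pMBRT against conventional PT). Without control 4, medians for conventional PT against control reversed to -0.11 (lipid handling, microglia, highest value leaving out 1 library 0.53), 0.85 (type I interferon, dendritic cells, lowest -1.18), 0.57 (proliferation, dendritic cells, lowest -0.64) and 0.42 (type I interferon, T/NK cells, lowest -0.77). For pMBRT against conventional PT, chemokines in macrophages reversed to 0.013 without conventional PT 1 (lowest leaving out 1 library -0.75), and proliferation in T/NK cells to 0.64 without pMBRT 4 (lowest -1.28).

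The microglial share after pMBRT (log2 fold change -2.61) lost its call with TMM over classes (-1.78), in late libraries only (-2.91), with named immune cells as denominator (-2.02) and at resolution 0.5 (-1.17), so 0 classes passed in each. In early libraries only 4 classes passed, with B cells at -2.74, macrophages at -1.08 and plasmacytoid dendritic cells at -4.93. For conventional PT, TMM over classes passed 1 class, microglia (-3.71). The NK share (-2.59) lost its call in late libraries only (-0.50), at resolution 0.5 (-2.60) and with the stricter cell filter (-2.49), so 0 subclasses passed in each, and corrected principal components passed 2, with CD4 T cells at 1.32.

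Leaving out 1 library, the microglial fold change after pMBRT ran from -2.90 to -2.38, that of NK cells from -3.29 to -2.13, of macrophages from -1.32 to -1.07 and of plasmacytoid dendritic cells from -4.95 to -2.49. After conventional PT microglia ran from -3.61 (without conventional PT 1) to -1.98 and plasmacytoid dendritic cells from -6.20 (without control 4) to 2.24 (without pMBRT 4). Classes past the threshold ran from 0 to 2 for pMBRT against control and 0 to 1 for conventional PT against control, and subclasses from 0 to 1 for pMBRT against control.

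Over all results and alternatives, gene counts moved in 73 cases and stayed in 106. Named genes weakened in 174, strengthened in 192, stayed in 3162 and reversed in 0. Gene lists reversed in 28, weakened in 129, strengthened in 1 and stayed in 504, and shares moved in 27, weakened in 19, strengthened in 10 and stayed in 833.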

Other observations

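The sterol test, the gene-count splits of the libraries and the splits within the library series were chosen only after the results were seen, whereas the 35 splits of the gene list counts were planned. In microglia after conventional PT, oxidative phosphorylation genes had negative fold changes in 27 of 27 members, whether or not they passed, with a median of -0.39 (camera adjusted p = 5.14e-08, adjusted p = 0.399 with an estimated correlation). The median was -0.07 without control 4 (adjusted p = 0.844). Lipid handling genes had a median of 0.40 there (camera adjusted p = 0.00825, adjusted p = 0.436 with an estimated correlation), and -0.11 without control 4 (adjusted p = 0.690). In T/NK cells after conventional PT, cytotoxicity genes had a median of 0.29 (14 of 21 positive, camera adjusted p = 0.00825, adjusted p = 0.150 with an estimated correlation), which lost its call without control 4 (adjusted p = 0.509). In macrophages, chemokine genes had a median of 0.85 after conventional PT (21 of 22 positive, camera adjusted p = 1.30e-05, adjusted p = 0.0955 with an estimated correlation).

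Proliferation genes had negative fold changes in microglia after pMBRT in 32 of 34 members, whether or not they passed. Their median was -0.55 (camera adjusted p = 0.000637, adjusted p = 0.586 with an estimated correlation), -0.27 in the early and -1.28 in the late libraries, and the call ended without control 4 (adjusted p = 0.130) or pMBRT 4 (0.138). In dendritic cells their median was -0.40 after pMBRT (camera adjusted p = 0.00857, adjusted p = 0.553 with an estimated correlation), -0.10 in the early and -1.49 in the late libraries, and the call ended without control 4 (adjusted p = 0.511) or pMBRT 4 (0.643). The chemokine list between pMBRT and conventional PT had a median of -0.55 in macrophages (camera adjusted p = 0.0124, adjusted p = 0.481 with an estimated correlation). Without conventional PT 1 its median was 0.01, whereas the test still pointed down (adjusted p = 0.000153).

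Cyp51, Idi1 and Hmgcs1 fell in dendritic cells after pMBRT, and a list of 23 sterol synthesis genes was then written, of which 9 had been seen. With those left out, the other 14 had negative values in 14 of 14 members in T/NK cells after pMBRT (median -0.57) and after conventional PT (-0.85), and in 14 and 12 of 14 in dendritic cells (-0.44 and -0.79). Medians were near 0 in microglia (0.04 and 0.02) and -0.12 and -0.13 in macrophages. A first run left out only 4 seen genes and passed with an estimated correlation (adjusted p = 0.0430, 0.0153, 0.0385 and 0.0153), and leaving out all 9 ended these calls, with a highest adjusted p of 0.131 and a lowest of 0.0726. A lower sterol synthesis in T/NK and dendritic cells after irradiation may be a hypothesis for new samples. The controls are shared by both comparisons, and the overlap was not simulated.

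Splits of the libraries into groups of the same sizes tested chance. For pMBRT against control, 1 of 35 splits gave as many genes in microglia as the real 137 (highest other 27). These 35 splits do not hold the library series fixed. Those with 1 late library in each group number 20, too few for a share under 0.05, and their highest other count in microglia was 2. It was 320 in dendritic cells, 32 in macrophages, 3 in T/NK cells and 56 for the gene lists. Over the 35, in dendritic cells 3 splits did (real 96, highest other 794), and in macrophages 4 (real 5, highest other 501), and chance is not excluded there. Where the real count is 0, all 35 splits give as many whatever the data, so nothing was tested. This holds for T/NK cells here (highest other 62). The split of control 1, 2 and 4 with pMBRT 4 gave the highest of these in dendritic cells, macrophages and T/NK cells. It points to a structure of the samples. Its other group is control 3 with pMBRT 1 to 3, whose library numbers lie closer to each other than to those of controls 1 and 2. The series covariate does not separate these early libraries, and the source of the structure was not tested. For conventional PT against control, 2 splits gave as many genes in microglia as the real 19 (highest other 21), and chance is not excluded. Macrophages, T/NK cells and dendritic cells had a real count of 0, so nothing was tested there (highest other 14, 2364 and 4), with control 4 grouped with conventional PT 2 and 3 in the highest. For pMBRT against conventional PT the real count was 0 in each class, so nothing was tested (highest other 0 in macrophages, 1566 in T/NK cells, 59 in microglia and 721 in dendritic cells), and the split by library series, pMBRT 4 and conventional PT 1 to 3 against pMBRT 1 to 3, gave the highest in microglia and dendritic cells. Within the late series edgeR called 2 genes in microglia and 5 in dendritic cells. For the gene lists 2 of 35 splits (real 53, highest other 56), 2 (real 50, highest other 56) and 7 (real 39, highest other 42) gave as many calls, and chance is not excluded.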
